A study of Mus musculus with 4 samples.

How the data were processed

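The samples were 1 normal mouse pancreas, 1 pancreas ligated by suture to bring on pancreatitis, 1 control KPC tumour and 1 KPC tumour treated with AF12198. Per the labels, tissue was digested for 90 minutes at 37°C with collagenases II and IV, passed through strainers of 100 and 40 µm, and made into 10x Genomics 3' libraries (v3 chemistry). The values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, deposited by the authors as 1 matrix per library, made with Cell Ranger 6.0.0 on genome build mm10 per the submitters' processing notes. The annotation release and the settings for calling cells are not given in the sources used here. Each matrix holds whole numbers for the same 32285 genes, with no row that lacks a gene name.

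In the order normal, ligated, control tumour and AF12198-treated tumour, the libraries hold 1844, 1165, 23189 and 21840 barcodes with 11350597, 5360054, 95779324 and 96886820 UMIs, and the lowest total of a barcode is 500, 500, 760 and 500. Cells were kept at 250 genes or more, 500 UMIs or more and at most 20% mitochondrial UMIs. Scrublet was run per library through Scanpy with its automatic threshold, and 1, 0, 2163 and 993 doublets were removed in this order. In the AF12198-treated library its threshold called only 1 cell, and by the rule set before the data were examined (under 0.5% of over 5000 cells) the 5% of cells with the highest scores were removed instead. The kept cells number 1771, 1124, 19235 and 18875, with 11235204, 5315805, 80398550 and 85735234 UMIs, medians of 1589, 2216, 2035 and 2298 UMIs and 798, 1101, 1009 and 991 genes per cell and median mitochondrial shares of 2.18, 1.252, 5.54 and 3.95%. Gm42418, which is known to collect ribosomal RNA reads, takes 7.70, 15.1, 4.56 and 4.90% of the UMIs.

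Counts were scaled to 10000 per cell, log-transformed, reduced to 2000 variable genes (without mitochondrial, ribosomal, Xist and Y genes) and 40 principal components, and clustered on 20 nearest neighbours with Leiden at resolution 1.0, all libraries together and without integration. This gave 37 clusters. A cluster took the name of 1 of 18 cell classes when at least 3 markers of the class were raised 2-fold and found in at least 10% of its cells. It stayed unnamed where a second class had at least 5 markers and 40% of its list raised too. These naming thresholds were chosen after the data had been examined. 30 clusters were named, in 14 classes, and 7 were left unnamed, which hold 33.2%, 4.00%, 2.16% and 2.89% of the cells. Names are written with the ending -like, since no cell was identified by other means.

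Leading genes of the main clusters were Dcn, Dpt and Col3a1 (fibroblast-like cluster 7) and Tnc, Serpine2 and Col8a1 (21), Il1r2, Hdc and Csf3r (neutrophil-like, 0), Tnf, Ccl3 and Il1a (1), Cxcl3, Acod1 and Cxcr2 (3), Retnlg and S100a8 (16) and Ngp, Camp and Ltf (34). Those of macrophage/monocyte-like clusters were Arg1, Mmp12 and Ccl24 (2), Ccl8, Ms4a7 and Ccl12 (4), Ccr2, Nrg1 and Lsmem1 (6), the interferon genes Ifi27l2a, Ifitm6 and Ifitm3 with Ms4a4c (13) and the cell-cycle genes Pclaf, Top2a and Mki67 (27). T-like clusters were led by Nkg7 and Cd8a (5), Tcf7 and Gimap3 (8), Il2ra and Tnfrsf4 (19) and the cell-cycle genes Hist1h1b, Top2a and Mki67 (26). Epithelial-like clusters were led by Tff1 and S100a6 (9), Ces1d and Dcdc2a (11) and Onecut2 and Cldn18 (14), and endothelial-like ones by Fabp4 and Plvap (12) and the lymphatic Ccl21a and Mmrn1 (29). The smaller classes were led by Plet1 and Ccl22 (dendritic-like, 10 and 22), Ms4a1 (B, 15), Gzma (NK or innate lymphoid, 17), Ctrb1 (acinar, 23), Igha (plasma, 24), Hba-a2 (erythroid, 25), Mcpt2 (mast or basophil, 28) and Ins2 (endocrine, 33).

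Each group is 1 library and cells are not replicates, so no test was made and no p-value is given. Shares of cells carry exact binomial intervals (Clopper-Pearson), and their ratios exact conditional ones. For each class with at least 25 cells in both libraries, UMIs were summed per library and expressed as CPM (the count divided by all UMIs of the class, on the customary CPM scale) with exact Poisson intervals, and 2 libraries were compared by the ratio of CPM with its exact conditional interval, and on the log2 scale by (CPM + 1). These intervals are 95% and cover counting error only. A fold against 0 UMIs is a lower bound against a floor of 3 counts in that library. The comparisons were ligated over normal, control tumour over ligated, since tumour cells were placed into a ligated pancreas, and AF12198-treated over control tumour.

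For 27 gene lists fixed before the data were examined, the median log2 ratio was taken over members with at least 5 UMIs in the 2 libraries together and 5 CPM in 1 of them, with an interval from 500 Poisson draws of the counts and a percentile among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries and is no test. A member is counted as higher or lower at 1.5-fold. Where members had 0 UMIs in a library, the median with these at their bound is given if it differs in the second decimal. Where the median of all measured genes lay more than 0.1 from 0, medians and counts of members are relative to it (not so for ligated over normal fibroblast-like and epithelial-like cells, where it was -0.03 and 0.08), while CPM and fold values of single genes are as counted. This step was chosen after the data had been examined. Il36g and Mx1 were not analysed here.

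Single genes are named by a rule: at least 30 CPM in the higher library, 20 UMIs in both together, a class CPM in the higher library of at least 0.5 times that over all its kept cells, and a ratio interval beyond 1.5-fold, ranked by log2 ratio. The 10 highest and 10 lowest are named in fibroblast-like cells and 4 and 4 in other classes, leaving out mitochondrial, ribosomal, X-inactivation, Y-linked, immunoglobulin and T cell receptor segment genes and unnamed gene models. A few genes that this rule or the lists would name are not reported here. Added to them are the 2 to 4 list members with the largest ratio at 20 UMIs or more, and 8 genes named in advance (Il1r1, Il1b, Il6, Cxcl1 and Nfatc1 to Nfatc4). Some clusters that differ between libraries are led by genes that the comparisons also name (Tnc, Col8a1, Tagln and Col12a1 of cluster 21; Arg1 of 2; Il1a of 1; Cxcl3 of 3; Ptgs2 of 0; Cd8a of 5; Ngp, Camp and Ltf of 34), so in these classes a gene and the cluster make-up move together.

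Free RNA was estimated per library and class from the level of markers of other classes against the pooled profile of the library. It came to 12.9, 7.04, 11.6 and 8.01% of the UMIs of fibroblast-like cells, and in the control and treated tumours to 12.1 and 5.37% in macrophage/monocyte-like, 21.2 and 10.8% in neutrophil-like and 15.0 and 6.54% in T-like cells. Transcript lengths (the median over a gene's transcripts), gene positions and shared sequence came from GENCODE vM21 on GRCm38 (mm10), matched by Ensembl ID for 32158 of 32285 genes (99.6%).

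In counts simulated from the fibroblast-like cells of the tumours, 95.5% of ratio intervals held the true value, and the naming rule recovered 98% of genes changed 2-fold, 99.5% of those changed 4-fold and named 0 unchanged genes. For the ligated over normal pancreas it recovered 39.5% and 95% and named 1 and 3 unchanged genes, and for the control tumour over the ligated pancreas 87.5% and 98%. Of 200 random lists in simulated data, 5% fell outside the central 95% of the random lists.

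Alternatives set before the data were examined were a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial) and none, doublets kept, Leiden resolutions 0.5 and 2.0, a TMM-type scaling factor, each cell weighted equally, a pseudocount of 10 CPM, a floor of 20 UMIs and 20 CPM, and subtraction of free RNA. Chosen after the data had been examined were an equal doublet share in both tumours, CPM without Gm42418 and mitochondrial genes, ratios relative to genes of like transcript length or to the other classes, and unnamed cells kept in the total of cells neither immune nor erythroid. Work was done with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9. Each deposited matrix was used. Splicing, strand and sequence variants cannot be read from summed UMIs and were not examined.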

Results

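Single-cell RNA sequencing was carried out on 4 mouse tissues, with 1 library per group: normal pancreas, pancreas with the duct occluded by suture ligation, a control KPC tumour and a KPC tumour treated with AF12198. KPC cells are a mouse pancreatic cancer line. They were placed into the ligated pancreas, where ligation induces pancreatitis, and the mice then received weekly intraperitoneal saline or AF12198, a small peptide antagonist of the interleukin-1 receptor IL1R1, until harvest at 4 weeks. After filtering, in this order, 1771, 1124, 19235 and 18875 cells remained, at medians of 1589, 2216, 2035 and 2298 UMIs per cell. Because each group was a single library, no difference below has a replicate check. Intervals are 95% and cover counting error only.

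The cell make-up differed between the 4 libraries. Fibroblast-like cells made up 5.42% (4.41 to 6.58) of the cells of the normal pancreas, 25.4% (22.8 to 28.0) of the ligated pancreas, 7.01% (6.65 to 7.38) of the control tumour and 2.77% (2.54 to 3.02) of the AF12198-treated tumour. Neutrophil-like cells numbered 0 of 1771 cells, which allows up to 0.208%, in the normal pancreas, and reached 9.61% (7.95 to 11.5) after ligation, 31.5% (30.9 to 32.2) in the control tumour and 39.5% (38.8 to 40.2) with AF12198. Macrophage/monocyte-like cells stood at 1.07%, 9.96%, 25.2% and 22.2% in the same order, and T-like cells at 0.791%, 5.43%, 12.5% and 13.4%. Epithelial-like cells, a class that holds ductal and tumour epithelium, stood in the opposite order, at 35.3%, 30.8%, 6.42% and 6.02%, as did endothelial-like cells, at 17.2%, 11.5%, 2.59% and 1.84%. Much of this goes with immune cells in the total: among named cells neither immune nor erythroid, epithelial-like cells were 54.8%, 44.6%, 39.4% and 48.6% and endothelial-like cells 26.6%, 16.6%, 15.9% and 14.8%. With unnamed cells kept in that total the epithelial-like shares were 36.1%, 42.2%, 34.8% and 39.4%, so that the order of normal and ligated pancreas turns. The lowest UMI total of a deposited barcode was 760 in the control tumour and 500 in the other libraries, a gap that can set the share of small cells such as neutrophils. Clusters left without a name held 33.2% of the cells of the normal pancreas, most of them low in UMIs with acinar and ductal markers together, and 4.00%, 2.16% and 2.89% of the others. Acinar-like cells, the enzyme-making cells that fill a normal pancreas, were 0.113% (0.0137 to 0.407) of that library, so its shares describe the cells that remained after digestion and filtering.

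**Figure D1:**
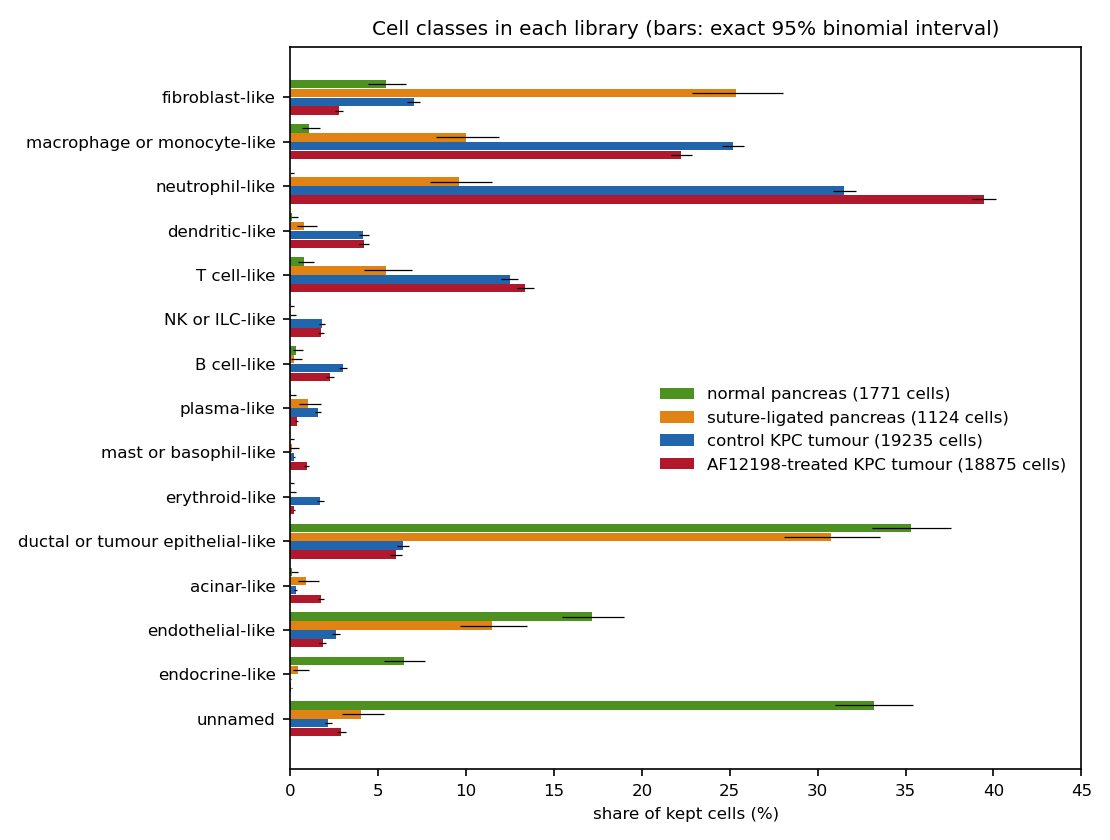
Share of kept cells (x axis, percent) in each cell class (y axis) for the 4 libraries, with exact 95% binomial intervals as error bars. Fibroblast-like cells peak after ligation at 25.4%.

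The ligated pancreas was set against the normal pancreas, 2 single libraries without a tumour. Fibroblast-like cells held a larger share after ligation, 4.68 (3.70 to 5.96) times that of the normal pancreas, and their inflammatory, myofibroblast and matrix genes stood higher. Saa3, an acute-phase serum amyloid, was at 835 CPM after ligation and had no UMI in the normal library, which makes it at least 161-fold higher against a floor of 3 counts in that library. The interleukin-6 gene Il6 stood at 312 against 39.8 CPM, 7.84-fold higher (5.18 to 12.5). Macrophage/monocyte-like and T-like cells held 9.29 (5.68 to 16.0) and 6.87 (3.80 to 13.3) times their normal shares. The fibroblast-like ratio came to 3.57 with the stricter cell filter, 3.06 with doublets kept and 3.04 at clustering resolutions 0.5 and 2.0, and the macrophage/monocyte-like ratio to 4.76 with the stricter filter.

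By list, the inflammatory cancer-associated fibroblast (CAF) genes had a median log2 ratio of 0.72 (0.44 to 0.97), above 99.98% of random lists of equal size and expression. Of 19 members, 10 stood higher and 2 lower by at least 1.5-fold. Their leading members were the neutrophil attractant Cxcl2 (611 against 15.6 CPM) and the monocyte attractant Ccl7 (285 against 31.2 CPM). The myofibroblastic CAF list had a median of 1.65 (1.11 to 2.32), or 1.12 with 2 members set at their bound, above each random list. Of 19 members, 13 stood higher and 3 lower. At the top were the matrix glycoprotein tenascin C, Tnc (at least 34.7-fold higher at 180.1 CPM), Cthrc1 (143 against 3.46 CPM), Ncam1 (169 against 5.20) and Col12a1 (142 against 5.20). For matrix genes the median was 0.86 (0.76 to 0.97), above each random list. Of 26 members, 18 stood higher and 5 lower. Among them Timp1 (1268 against 53.7 CPM; 23.6-fold higher, 16.6 to 34.8), Col1a1 (15014 against 2857 CPM; 5.25-fold higher, 5.00 to 5.52) and Fn1 (2165 against 403 CPM) stood higher, and the protease Mmp3 (65.6 against 256 CPM) lower. Targets of IL-1 and NF-kB had a median of 1.27 (1.12 to 1.60), above each random list. Of 24 members, 16 stood higher and 1 lower, with Cxcl5 (129 against 3.46 CPM) and Lcn2 (47.4 against 1.73) among the leading members. Genes known to respond to calcineurin and NFAT had a median of 1.20 (0.82 to 1.58), or 0.90 with 1 member set at the bound, above each random list. Of 16 members, 10 stood higher and 2 lower. Examples were Ccl2 (464 against 71.0 CPM), the calcineurin regulator Rcan1 (129 against 22.5 CPM) and the prostaglandin synthase Ptgs2 (429.5 against 90.0 CPM). The components of that pathway had a median of 0.36 (-0.01 to 0.57), above 99.1% of random lists. TGF-beta response genes stood at 0.71 (0.40 to 0.98), above 99.98% of random lists, led by Ltbp2 (86.9 against 1.73 CPM). Proliferation genes stood at 1.30 (0.93 to 2.51), or 0.76 with 5 members set at their bound, above each random list, led by Birc5 (15.6 against 0 CPM). Genes known to respond to tissue dissociation had a median of 0.38 (0.28 to 0.49), above 99.0% of random lists, with Ier3 (503 against 189 CPM) and Dnajb1 (245 against 98.7).

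Ranked over all genes, the largest ratios higher after ligation in fibroblast-like cells, after Saa3 and Tnc, were those of Serpinb2, Col24a1, Thbs4, Ptx3, Chl1, Cxcl9 and Clca3a2, each without a UMI in the normal library and 9.12 to 24.5 times its floor at the least. Sfrp2, a secreted Wnt modulator, followed (274 against 3.46 CPM). The lowest were the cartilage matrix gene Comp (1.56 against 45.02 CPM), Lamc3, P2ry1, Robo2, Tdo2, Lsamp, Kcnn3, the lipid carrier Apod (77.1 against 698 CPM), Hsd11b1, which makes active glucocorticoid (49.5 against 424 CPM; 8.58-fold lower, 6.74 to 10.99), and Ogfrl1. Their log2 ratios ran from -4.17 for Comp to -3.00 for Ogfrl1.

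In epithelial-like cells, of which cluster 11 held nearly all in both libraries, ligation went with higher IL-1 and NF-kB targets, at a median of 0.71 (0.64 to 0.85), above each random list. Of 20 members, 13 stood higher and 0 lower, led by Cxcl5 (21.6 against 0 CPM) and Vcam1 (26.1 against 3.34). MHC class II genes stood at 1.99 (1.49 to 2.41), above each random list, with Cd74 (80.9 against 8.69 CPM) and H2-Ab1 (21.1 against 1.78). Ptgs2 (12.1 against 0 CPM) and Saa3 (13.0 against 0.446 CPM) stood higher too, but nothing of either difference was left once the pooled profile of the library was subtracted. Genes of acinar-to-ductal change had a median of -0.02 (-0.04 to 0.32), above 45.1% of random lists. At their top were the ductal regulator Onecut2 (102 against 20.4 CPM), Muc6 (14.4 against 0 CPM), Reg3b (10.3 against 0.334) and Cd44 (105 against 49.0). The largest single ratios were those of Gkn3 (at least 277-fold higher), Dmbt1, Ltf and the laminin gene Lamb3 (36.0 against 4.57 CPM). The lowest were those of Igfbpl1, Lamc3, Lce6a and Hopx (8.99 against 36.4 CPM). In endothelial-like cells the interferon response stood lower after ligation, with a median relative to all genes of -1.35 (-1.73 to -1.08), below each random list. Of 17 members, 1 stood higher and 15 lower, among them Ifit3 (11.8 against 67.2 CPM), Isg15 (73.5 against 333) and Cxcl10 (64.6 against 260.3). Ifi27l2a stood higher (49.96 against 4.198 CPM). Matrix genes had a median of 0.84 (0.44 to 1.36), above each random list, led by Fn1 (347 against 39.2 CPM) and Col3a1 (106 against 14.0), of which the latter was at the level of free RNA. Blood vessel genes had a median of 0.03 (-0.36 to 0.24), above 69.4% of random lists. Among them were the leukocyte adhesion molecules Sele (232 against 25.2 CPM) and Selp (1134 against 351) and Angpt2 (61.7 against 18.2 CPM), all higher, and the capillary gene Plvap (919.8 against 2357 CPM), which stood lower. Sema3a, Hgf, Klrb1f and Adamtsl1 led the genes higher after ligation, at 70.5 to 194 CPM. Ifi208, Olfr655, Cyp26b1 (44.1 against 779 CPM) and Nostrin led those lower. Lymphatic cluster 29 held 38 of the 129 ligated endothelial-like cells and 3 of the 304 normal ones.

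These values rest on 96 normal and 285 ligated fibroblast-like cells. In Poisson counts simulated at this depth, among genes at 30 CPM or more, the naming rule recovered 39.5% of those changed 2-fold and 95% of those changed 4-fold. The Cxcl9 log2 ratio of 5.76 came to 1.93 when called doublets were kept and the cells clustered again.

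Tumour cells had been placed into a ligated pancreas, so the control tumour was set against the ligated pancreas. The tumour held fewer fibroblast-like cells, 0.276 (0.243 to 0.315) times the share of the ligated pancreas, and more macrophage/monocyte-like (2.53 (2.09 to 3.07) times), neutrophil-like (3.28 (2.71 to 4.01)) and T-like cells (2.30 (1.78 to 3.01)). Among named cells neither immune nor erythroid they were not fewer, at 43.0% (41.2 to 44.7) in the tumour against 36.8% (33.4 to 40.3), or 37.9% (36.3 to 39.6) against 34.8% (31.5 to 38.1) with unnamed cells kept. Its fibroblast-like cells carried more myofibroblast transcripts and about as much of the inflammatory list. Epithelial-like cells of the tumour carried more mesenchymal and cell-cycle transcripts, its macrophage/monocyte-like cells more inflammatory and interferon-induced chemokine transcripts, and its T-like cells more granzyme and perforin and less interleukin-17. Medians here and in the AF12198 comparison are given relative to the median of all measured genes in the class, which stood at 0.11 in fibroblast-like, -0.11 in macrophage/monocyte-like, 0.34 in neutrophil-like, 0.18 in T-like, -0.26 in epithelial-like and -0.14 in endothelial-like cells.

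In fibroblast-like cells the myofibroblastic CAF list had a median of 1.42 (1.26 to 1.56; 1.53 before the shift), above each random list. Of 20 members, 15 stood higher and 1 lower. The collagens Col8a1 (613 against 88.0 CPM; 6.96-fold higher, 5.98 to 8.16) and Col12a1 (553 against 142 CPM), the contractile gene Tagln (534 against 103 CPM; 5.18-fold higher, 4.49 to 5.99) and Tnc (746 against 180.1 CPM) led it. All 4 are also leading genes of fibroblast-like cluster 21, which held cells of the tumours only. It raised 15 of 16 fibroblast markers, none among its 10 leading genes, and 5 of 13 markers of pericytes or smooth muscle, so such cells are not excluded. The inflammatory CAF list had a median of 0.01 (-0.04 to 0.14; 0.12 before the shift), above 15.8% of random lists. Of 19 members, 3 stood higher and 4 lower. The hyaluronan synthase Has2 (67.3 against 38.0 CPM), Il11 (18.3 against 6.77) and Saa3 (1426 against 835) stood higher and Clec3b (222 against 753 CPM) lower. The calcineurin/NFAT response had a median of 0.61 (0.48 to 0.75), above 99.9% of random lists. Of 16 members, 8 stood higher and 0 lower, with the G-protein regulator Rgs2 (106 against 19.3 CPM) and the nuclear receptor Nr4a3 (448 against 139 CPM) as examples. Its components stood at 0.19 (0.03 to 0.38), above 78.8% of random lists. IL-1 and NF-kB targets stood at 0.08 (0.01 to 0.21), above 27.2% of random lists. TGF-beta response genes stood at 0.56 (0.44 to 0.66), above 99.6% of random lists. Matrix genes stood at 0.14 (0.05 to 0.18), above 33.6% of random lists. MHC class I genes had a median of 1.10 (0.95 to 1.19), above each random list, with Psmb8 (76.7 against 19.8 CPM).

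The antigen-presenting CAF list (median 4.09 (3.70 to 4.32), or 3.73 with 1 member set at the bound, above each random list) and MHC class II genes (4.16 (3.77 to 4.50), above each random list) stood far higher in the tumour. For H2-Ab1 (170.0 against 5.73 CPM), H2-Aa and Cd74 no difference was left after subtraction of the pooled profile of the library, where macrophage/monocyte-like cells are abundant. The mesothelial marker Upk3b (42.5 against 0.521 CPM; 81.6-fold higher, 14.6 to 3227) kept its difference there. Neutrophil genes moved the same way in this class (median 2.39 (2.04 to 2.68), above each random list; Camp (57.5 against 0 CPM) and Ngp (56.5 against 0.521)). The 10 genes with the largest ratios higher in the tumour were Camp (at least 36.8-fold higher), Upk3b, the BMP antagonist Grem1 (79.7 against 2.08 CPM; 38.3-fold higher, 14.9 to 141), the osteopontin gene Spp1 (1538 against 86.9 CPM; 17.7-fold higher, 15.2 to 20.7), Lrrn4, Cadm4, Arxes2, Ch25h, the B cell attractant Cxcl13 (93.4 against 6.25 CPM) and Dio3. The lowest were the adipocyte marker Car3 (0.0727 against 45.8 CPM; 630.0-fold lower, 110.2 to 25164), Inmt, Col4a4, Galnt15, Tek, AY036118, Crabp2, Abca8a, Cyp27a1 and the actin-severing gelsolin Gsn (1311 against 8331 CPM; 6.35-fold lower, 6.22 to 6.49). Their log2 ratios were -5.56 to -2.78 relative to all genes. AY036118 is known to collect ribosomal RNA reads.

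Most ligated macrophage/monocyte-like cells lay in cluster 4, and those of the control tumour in clusters 4 and 6. Inflammatory myeloid genes had a median of 1.68 (1.41 to 1.98), or 1.49 with 1 member set at the bound, above each random list. Of 18 members, 16 stood higher and 2 lower. At the top were the T cell attractants Cxcl9 (759.9 against 13.4 CPM; 56.8-fold higher, 22.2 to 208) and Cxcl10 (429 against 26.8 CPM), the nitric oxide synthase Nos2 (15.2 against 0 CPM) and Il6 (51.8 against 3.35 CPM). Interferon response genes had a median of 0.85 (0.70 to 1.54), above each random list. They went both ways, Gbp2 (281 against 13.4 CPM) higher and Ifit3 (5.03 against 46.8 CPM) lower. Tumour-macrophage genes had a median of -0.05 (-0.29 to 0.29), above 6.32% of random lists, with the collagenase Mmp13 (151 against 10.0 CPM) higher and the scavenger receptor Cd163 (7.16 against 83.6 CPM) and Gpnmb (47.9 against 231 CPM) lower. Tnfrsf9, Ccl24 (303 against 3.35 CPM) and Dnase1l3 led all genes with Cxcl9. The acinar enzyme genes Clps (14.9 against 776 CPM), Try4, Zg16 and Pla2g1b stood lowest, as they did in other classes. In fibroblast-like cells acinar enzyme genes had a median of -4.76 (-5.10 to -4.64), below each random list.

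The T-like cells of the ligated pancreas, 61 cells of which 50 lay in cluster 8, differed in kind from those of the tumour, most of which lay in the Cd8a-positive cluster 5. Cytotoxic and checkpoint genes had a median of 1.16 (0.82 to 2.0), or 0.75 with 4 members set at their bound, above 99.9% of random lists. Of 18 members, 13 stood higher and 2 lower. Genes under 1000 bases exceeded those over 3000 by 1.43 in this class, which is as large as that median. Granzyme B, Gzmb, was at 175 CPM in the tumour and at least 3.38-fold higher, and perforin, Prf1, at least 1.94-fold higher, followed by Gzma (172 against 17.2 CPM). Gzmk (23.7 against 0 CPM) was below the level that 3 counts would give in the ligated library. Regulatory and Th17 genes had a median of -1.78 (-2.17 to -0.59), above 0.0100% of random lists. The interleukin-17 gene Il17a was at 8.18 against 1328 CPM, 162-fold lower (112 to 236), while Tnfrsf18 (186 against 17.2 CPM) stood higher. Cd8a (at least 10.2-fold higher), Pgk1, Aprt and Mtpn led the genes higher in the tumour, and Cela2a, Cd163l1, Il17a and Cela3b those lower.

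Ligated neutrophil-like cells lay mostly in cluster 3 (80 of 108) and those of the control tumour in cluster 0 (5474 of 6064). Neutrophil genes had a median of 0.27 (0.12 to 0.46), above 97.49% of random lists. The granule genes of immature neutrophils Ngp (1040.3 against 6.51 CPM), Ltf (533 against 6.51 CPM) and Camp (601 against 39.0 CPM; 15.4-fold higher, 7.07 to 42.0) and the sialic acid receptor Siglecf (167 against 26.0 CPM) stood higher. Cluster 34, which held 52 cells of the control tumour and 0 of the others, carried 94.9, 85.6 and 97.0% of the control UMIs of Ngp, Ltf and Camp. In the other control cells these genes were at 54.6, 79.2 and 18.5 CPM, so Camp was not higher there than after ligation. The proliferation list stood at 3.07 (2.98 to 3.26). With 13 members at their bound only the shift of all genes (-0.34) was left, so no rise is shown. Top2a and Stmn1 led, at 33.5 and 32.4 against 0 CPM. Chil3 (at least 15.1-fold higher), Cd177, Ngp and Hsph1 led all genes. Cluster 34 carried 48.6% of the control UMIs of Chil3, and without it Chil3 and Top2a were at 156 and 20.8 CPM. The acinar genes Cela2a, Cela3b, Pla2g1b, with Ttc21a, stood lowest. The epithelial-like cells of the ligated library lay mostly in cluster 11, and those of the tumour mostly in clusters 9 and 14. In this class the EMT list had a median of 3.18 (2.63 to 3.82), above each random list. Of 16 members, 13 stood higher and 0 lower. It was led by S100a4 (554 against 8.09 CPM), the receptor kinase Axl (138 against 1.80 CPM), Prrx1 (32.0 against 0 CPM) and vimentin, Vim (2642 against 89.9 CPM; 29.4-fold higher, 25.6 to 33.9). Proliferation genes stood at 4.15 (3.59 to 4.45), above each random list, with Ube2c (138 against 1.80 CPM) and Rrm2 (77.2 against 0.899). MHC class II genes stood at 3.62 (3.46 to 4.29), above 99.99% of random lists, with H2-Aa (313 against 10.3 CPM) and H2-Eb1 (227 against 13.9). Epithelial identity genes had a median of -0.07 (-0.17 to 0.03), above 4.76% of random lists, with mesothelin, Msln (320.4 against 0 CPM), higher and claudin 3, Cldn3 (17.96 against 472 CPM), lower. Acinar-to-ductal genes had a median of 0.83 (0.50 to 1.30), above 87.7% of random lists, with the gastric gene Tff1 (155 against 0 CPM) and Onecut2 (831 against 102 CPM) higher and Muc6 (1.16 against 14.4 CPM) lower. Lgals2, Cldn18, Apob and Cdkn2a, at 336 to 755 CPM in the tumour with at most 1 UMI after ligation, led all genes. Adam33, Fmo2, Fgfr3 and AI838599 stood lowest.

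Endothelial-like cells of the tumour stood higher in proliferation genes, at a median of 1.90 (1.71 to 3.10), above each random list. Of 20 members, 19 stood higher and 0 lower, among them Birc5 (50.05 against 0 CPM). MHC class II genes stood at 3.11 (2.56 to 3.52), or 2.59 with 1 member set at the bound, above each random list, with H2-Ab1 (276 against 26.4 CPM), but H2-Aa (259 against 26.4 CPM) did not keep its direction after subtraction of the pooled profile. Blood vessel genes had a median of 0.05 (-0.05 to 0.36), above 31.6% of random lists. The tip cell genes Apln (197 against 2.94 CPM) and Esm1 (248 against 35.3 CPM; 7.04-fold higher, 3.99 to 13.7) and Cxcr4 (114 against 26.4 CPM) stood higher and Sele (44.6 against 232 CPM) lower. The globin genes Hbb-bs and Hbb-bt, Mki67 (80.8 CPM, at least 9.16-fold higher) and Cd276 led all genes. The acinar genes Try4, Ctrl, Clps and Zg16 stood lowest. The 61 to 346 cells of each class in the ligated library set the width of these intervals.

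The AF12198-treated tumour was set against the control tumour. The treated tumour held fewer fibroblast-like cells, 0.395 (0.357 to 0.438) times the share of the control tumour, and more neutrophil-like cells (1.252 (1.21 to 1.30) times). Shares of macrophage/monocyte-like (0.884 (0.848 to 0.921)), T-like (1.07 (1.01 to 1.13)) and epithelial-like cells (0.937 (0.864 to 1.02)) differed less, and endothelial-like cells stood at 0.710 (0.617 to 0.816) times. Among named cells neither immune nor erythroid, fibroblast-like cells were 22.4% against 43.0% (18.1% against 37.9% with unnamed cells kept) and epithelial-like cells stood higher, at 48.6% (46.5 to 50.6) against 39.4% (37.7 to 41.1), or 39.4% against 34.8%. Without neutrophils the macrophage/monocyte-like share was 36.7% in both. Within fibroblast-like cells, contractile myofibroblast genes and several chemokines stood higher, while the inflammatory CAF and IL-1/NF-kB lists had medians near that of all genes. The calcineurin/NFAT response list had a median below that of all genes, with 4 of 16 members lower and 3 higher. Relative to genes of like transcript length these 3 lists stood alike, at -0.18, -0.19 and -0.21. In CPM, Il6 was lower in each main class and Nfatc2 in all but epithelial-like cells, while Il1r1 of fibroblast-like cells was at the same level. The macrophage/monocyte-like share ratio became 1.03 with the stricter cell filter and the T-like ratio 0.840 at clustering resolution 0.5.

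In fibroblast-like cells the median ratio of all genes was -0.26 on the log2 scale. The calcineurin/NFAT response list stood at -0.32 (-0.39 to -0.22; -0.59 before the shift), above 0.0400% of random lists. Of 16 members, 3 stood higher and 4 lower. Without 6 immediate-early genes, among them Rgs2 and Ptgs2, the median was -0.037 (-0.20 to 0.14), with 5 of 10 members below 0. Rgs2 (49.9 against 106 CPM; 2.12-fold lower, 1.87 to 2.42), the adhesion molecule Vcam1 (114 against 236) and Ptgs2 (328 against 632; 1.93-fold lower, 1.83 to 2.03) stood lower, and interleukin-11, Il11 (46.3 against 18.3 CPM; 2.52-fold higher, 2.12 to 3.01), higher. Pathway components had a median of -0.21 (-0.28 to -0.09), above 1.92% of random lists. The calcineurin subunit Ppp3r1 (63.6 against 126 CPM), Plcg1 (17.5 against 30.5) and Orai1 (8.94 against 15.1) stood lower. Genes known to respond to tissue dissociation stood lower in this class as well, at a median of -0.26 (-0.32 to -0.21), above 0.185% of random lists. Examples were Zfp36 (490.2 against 1423 CPM) and Ier2 (250.2 against 702). The calcineurin/NFAT response list shares Nr4a1 with them. The inflammatory CAF list had a median of -0.09 (-0.15 to -0.02; -0.35 before the shift), above 3.60% of random lists. Of 19 members, 4 stood higher and 1 lower, with Dpt (727 against 1407 CPM) lower and Ccl2 (822 against 501 CPM; 1.64-fold higher, 1.58 to 1.70) higher. IL-1 and NF-kB targets had a median of -0.0041 (-0.17 to 0.05; -0.27 before the shift), above 13.7% of random lists. Of 25 members, 6 stood higher and 5 lower. The NF-kB pathway regulators Birc3 (33.5 against 86.5 CPM) and Tnfaip3 (81.8 against 195 CPM; 2.38-fold lower, 2.16 to 2.63) stood lower, as did Csf3 (0.344 against 5.82 CPM), counted at 2 UMIs in the treated tumour. Under another scaling factor between the libraries (TMM-type) the medians of these 3 lists before the shift were -0.39, -0.14 and -0.07.

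The myofibroblastic CAF list stood at 0.51 (0.36 to 0.53; 0.24 before the shift), above 93.7% of random lists. Of 20 members, 10 stood higher and 0 lower. The contractile genes Cnn1 (29.1 against 8.14 CPM), Tpm2 (577 against 235) and Tagln (1110.4 against 534 CPM; 2.08-fold higher, 2.01 to 2.15) led it, with Lrrc15 (58.1 against 26.5 CPM). Chemokines and growth factors had a median of 0.46 (0.38 to 0.53), above 98.3% of random lists, but short transcripts exceeded long ones by 0.778. Of 24 members, 9 stood higher and 1 lower, among them Cxcl3 (27.2 against 6.98 CPM) and Cxcl14 (1078 against 431); Cxcl3 stood higher in 12 of the 13 classes. Matrix genes had a median of 0.04 (0.01 to 0.07), above 4.96% of random lists. Elastin, Eln (408 against 949.8 CPM), Col6a2 (551 against 991 CPM) and Mmp14 (365 against 629.6) stood lower and Mmp3 (451 against 278 CPM) higher. The antigen-presenting CAF list had a median of 0.24 (0.18 to 0.32), above 74.4% of random lists. MHC class II genes stood at 0.27 (0.22 to 0.35), above 73.1% of random lists (H2-DMb1 (25.1 against 36.1 CPM) and H2-Eb1 (161 against 119.9)), but H2-Eb1 turned to -0.38 on the log2 scale at an equal doublet share. Proliferation genes stood at 0.33 (0.30 to 0.46), above 99.3% of random lists. IL-1 ligands and receptors had a median of 0.05 (-0.13 to 0.13), above 59.3% of random lists. Interleukin-1 alpha, Il1a (24.9 against 10.8 CPM), and the interleukin-33 receptor Il1rl1 (30.3 against 13.7 CPM) stood higher and Traf6 (7.05 against 13.3 CPM) and Il1rn (71.4 against 118) lower. Acinar enzyme genes, which fibroblasts are not known to use, had a median of 1.98 (1.61 to 2.28), above each random list.

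**Figure D2:**
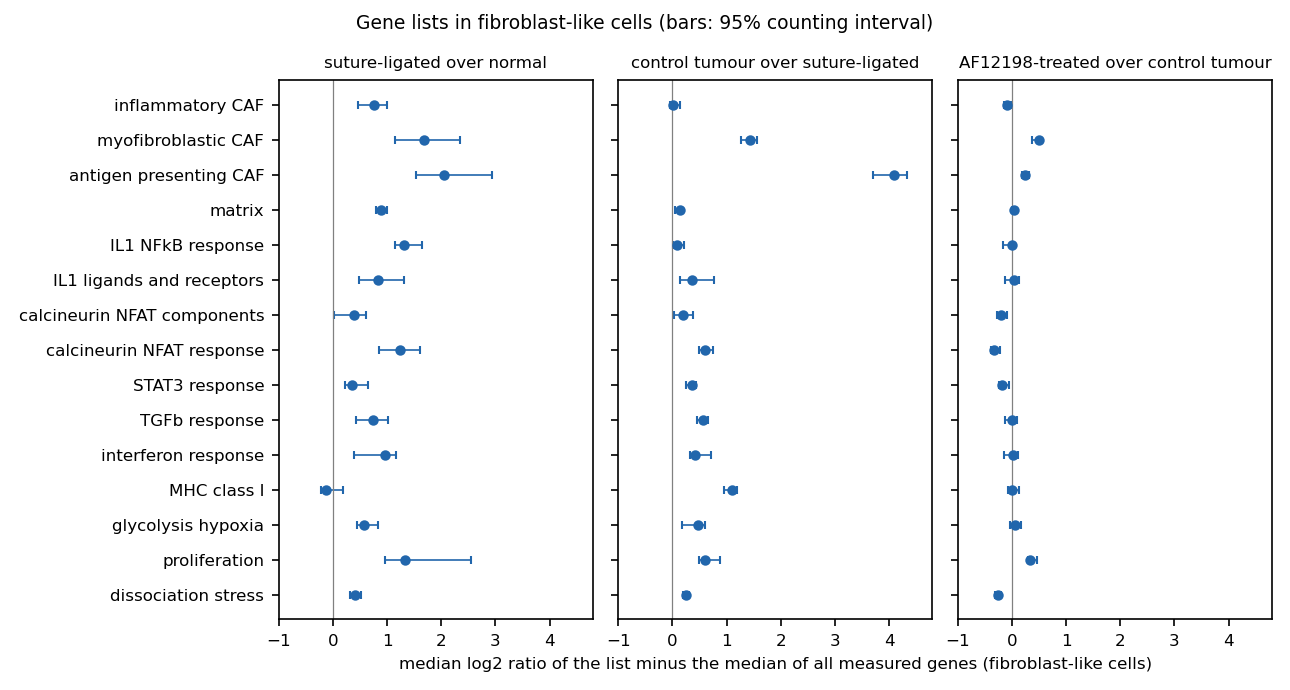
Median log2 ratio of 15 gene lists in fibroblast-like cells minus the median of all measured genes (x axis), for the 3 comparisons, with 95% counting intervals as error bars. The myofibroblastic list lies above 0 in all 3 comparisons and the calcineurin/NFAT response list at -0.32 in the AF12198 comparison.

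Over all genes, among the 10 with the largest ratios higher in fibroblast-like cells of the treated tumour were Gng5, Ssr4, Grpel1, the smooth muscle actin Actg2 (70.2 against 22.0 CPM), Gsdme, Atp5g1, Ppib, Elob and Nme2. The 10 lowest were the cathelicidin gene Camp (0.860 against 57.5 CPM; 66.8-fold lower, 28.5 to 206), the BMP antagonist Grem1 (9.11 against 79.7 CPM; 8.75-fold lower, 6.64 to 11.8), Mtss1, the non-coding AC160336.1, Cxcl13 (23.0 against 93.4 CPM; 4.06-fold lower, 3.39 to 4.88), Col24a1, the lipoprotein lipase Lpl (246 against 815 CPM), Matn4, Col4a5 and Ogt. Camp is a granule gene of immature neutrophils and was at 601 CPM in the neutrophil-like cells of the control tumour. Of the 9 higher genes measured in at least 5 other classes, 9 stood higher in most of those, and of the 5 such lower genes, 5 stood lower. Short transcripts stood higher across the treated library: the median of genes with transcripts under 1000 bases exceeded that of genes over 3000 bases by 0.778 in fibroblast-like cells and by 0.630 to 1.29 over the 13 classes. Trends of this kind were not limited to the treated library: the same difference ran from 0.0952 to 1.43 (T-like cells) over 6 classes for the control tumour over the ligated pancreas, and from -0.885 to 0.0897 over 3 classes for the ligated over the normal pancreas.

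**Figure D3:**
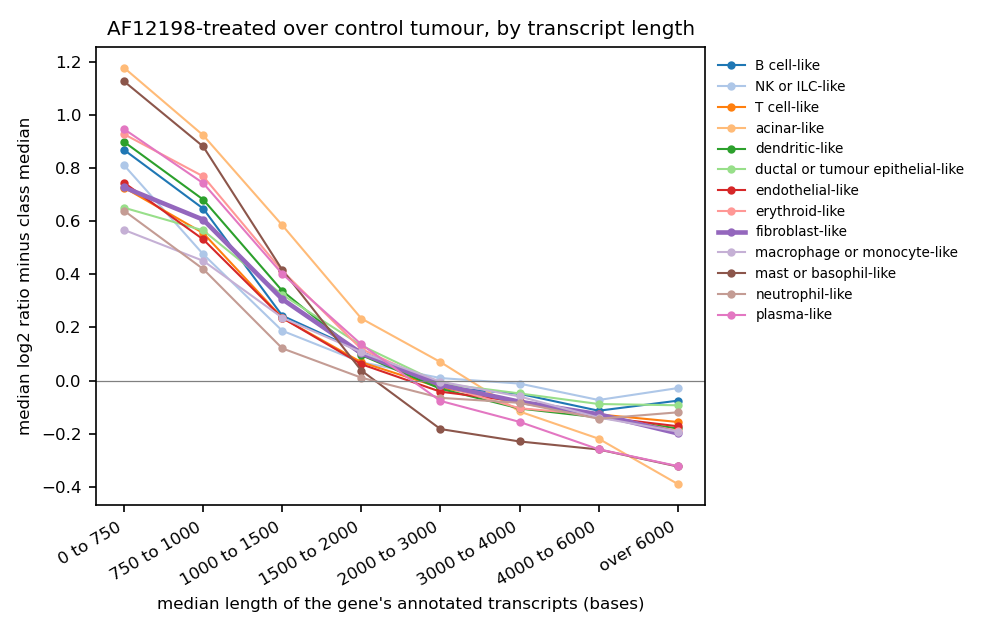
Median log2 ratio of the AF12198-treated over the control tumour in bins of median transcript length (x axis, bases, bins evenly spaced), minus the median of the class, with a line for each of 13 cell classes. The lines fall from short to long transcripts in each class, with 0.630 the smallest difference between genes under 1000 and over 3000 bases.

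The genes of the pathway under study were followed in fibroblast-like cells of the normal, ligated, control and AF12198-treated libraries in this order. Intervals are exact Poisson, or the CPM of 3 counts without a UMI. Il1r1 (ENSMUSG00000026072; chromosome 1, 40225080 to 40317257), the receptor that AF12198 blocks, was at 86.6 (64.3 to 114), 152 (135 to 170.0), 156 (149 to 162) and 158 (148 to 168) CPM, a ratio of 1.01 (0.937 to 1.10) between the tumours. Interleukin-6, Il6 (ENSMUSG00000025746; chromosome 5, 30013114 to 30019981), was at 39.8 (25.2 to 59.8), 312 (288 to 338), 449 (438 to 460.3) and 265 (252 to 279) CPM, 1.69-fold lower (1.60 to 1.79) with AF12198. The neutrophil attractant Cxcl1 (ENSMUSG00000029380; chromosome 5, 90891241 to 90893115) was at 513 (456 to 574), 1019 (974 to 1065), 668 (654 to 681) and 989.7 (964 to 1016) CPM, 1.48-fold higher (1.43 to 1.53) with AF12198. Il1b (ENSMUSG00000027398; chromosome 2, 129364570 to 129371139) was at 0 (up to 5.20), 27.6 (20.7 to 36.1), 304 (295 to 313) and 201 (189.8 to 213) CPM, and none of it was left after subtraction of the pooled profile of the library. Of the NFAT transcription factors, Nfatc1 (ENSMUSG00000033016; chromosome 18, 80606205 to 80713071) was at 20.8 (10.7 to 36.3), 66.1 (55.1 to 78.7), 105 (99.8 to 111) and 66.5 (60.1 to 73.5) CPM and 1.58-fold lower (1.41 to 1.77) with AF12198. Nfatc2 (ENSMUSG00000027544; chromosome 2, 168476410 to 168601657) was at 1.73 (0.0438 to 9.65), 6.77 (3.60 to 11.6), 11.1 (9.43 to 13.0) and 3.44 (2.10 to 5.31) CPM, 3.24-fold lower (2.02 to 5.45) with AF12198, on 20 UMIs. Nfatc3 (ENSMUSG00000031902; chromosome 8, 106058840 to 106130537) was at 29.4 (17.1 to 47.1), 40.1 (31.6 to 50.1), 49.0 (45.4 to 52.9) and 34.4 (29.8 to 39.5) CPM. Nfatc4 (ENSMUSG00000023411; chromosome 14, 55823144 to 55833943) was at 24.2 (13.3 to 40.7), 39.6 (31.2 to 49.5), 49.2 (45.6 to 53.1) and 40.2 (35.2 to 45.7) CPM. Relative to all genes the log2 ratios of the treated over the control tumour were 0.28 for Il1r1, -0.49 for Il6, 0.83 for Cxcl1, -0.39 for Nfatc1, -1.19 for Nfatc2, -0.23 for Nfatc3 and -0.02 for Nfatc4. Coordinates (GRCm38) span the whole gene, in each case protein-coding.

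In the other main classes these genes stood as follows in the ligated, control and treated libraries. For epithelial-like and endothelial-like cells the normal pancreas is first. Without a UMI, the CPM of 3 counts stands in brackets. Il1b came mostly from neutrophil-like (13929.7, 13218 and 11877 CPM) and macrophage/monocyte-like cells (779, 3255 and 3697). It was at 224, 489 and 327 in T-like, 0.223, 35.1, 199 and 181 in epithelial-like and 2.80, 85.2, 459.8 and 252 in endothelial-like cells. With free RNA subtracted, these control tumour rises and the T-like fall with AF12198 turned. Il1r1 was highest in endothelial-like cells (81.2, 112, 50.05 and 51.5), and lower in epithelial-like cells (18.9, 18.9, 22.2 and 16.1). It was lower too in T-like (34.5, 3.44 and 7.50), macrophage/monocyte-like (3.35, 2.52 and 1.87) and neutrophil-like cells (0 (up to 19.5), 3.58 and 1.34). Il6 was at 36.4, 55.8, 105 and 46.0 in endothelial-like and 3.35, 51.8 and 25.4 in macrophage/monocyte-like cells. It was at 0 (up to 19.5), 20.03 and 4.02 in neutrophil-like, 0 (up to 51.7), 9.65 and 1.05 in T-like and 0.111, 3.15, 3.91 and 3.27 in epithelial-like cells. Cxcl1 was at 144, 259, 121 and 101 in epithelial-like and 247, 283 and 154 in neutrophil-like cells. The level was 137, 249.8 and 133 in macrophage/monocyte-like, 111, 106, 95.6 and 91.1 in endothelial-like and 17.2, 42.2 and 14.1 in T-like cells. Nfatc1 was at 172, 162 and 109.6 in T-like and 39.2, 206, 102 and 71.3 in endothelial-like cells. It was at 71.6, 103 and 95.7 in neutrophil-like, 73.6, 48.5 and 42.2 in macrophage/monocyte-like and 29.9, 32.4, 17.6 and 16.3 in epithelial-like cells. Nfatc2 was at 138, 48.9 and 43.8 in T-like and 1.40, 49.96, 15.4 and 3.22 in endothelial-like cells. It was at 46.8, 25.6 and 15.1 in macrophage/monocyte-like, 16.9, 27.9, 6.78 and 8.49 in epithelial-like and 0 (up to 19.5), 6.13 and 5.20 in neutrophil-like cells. Nfatc3 stood at 224, 179.8 and 136 in T-like and 47.7, 49.0, 64.6 and 36.4 in epithelial-like cells. It was at 46.2, 55.8, 69.4 and 40.0 in endothelial-like, 53.5, 44.4 and 27.8 in macrophage/monocyte-like and 26.0, 47.9 and 34.9 in neutrophil-like cells. Nfatc4 stood at 3.12, 3.60, 0.733 and 0.545 in epithelial-like and 4.198, 2.94, 1.98 and 2.76 in endothelial-like cells. Its level was 34.5, 0.491 and 0.117 in T-like, 0 (up to 10.0), 0.726 and 0.262 in macrophage/monocyte-like and 0 (up to 19.5), 1.02 and 0.168 in neutrophil-like cells.

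Macrophage/monocyte-like cells of the control tumour lay mostly in clusters 4 and 6, those of the treated tumour in clusters 2, led by Arg1, and 13. Inflammatory myeloid genes had a median of 0.29 (0.26 to 0.37; -0.01 before the shift), above 80.1% of random lists. Of 17 members, 5 stood higher and 2 lower. Among them Cxcl3 (188 against 82.7 CPM) and Il1a (207 against 115) stood higher and Il6 (25.4 against 51.8 CPM) and Ptgs2 (1365 against 2525) lower. Tumour-macrophage genes had a median of 0.15 (0.06 to 0.20), above 63.6% of random lists. Arginase 1, Arg1 (1345 against 700.2 CPM; 1.92-fold higher, 1.88 to 1.96), and osteopontin, Spp1 (1315 against 704 CPM; 1.87-fold higher, 1.83 to 1.90), stood higher and Il10 (27.8 against 63.5 CPM) and Retnla (11.7 against 23.1) lower. MHC class II genes had a median of 0.35 (0.33 to 0.36), above 67.6% of random lists. The T cell attractant Ccl5 (343 against 64.2 CPM; 5.34-fold higher, 5.05 to 5.66), Gng5, Gapdh and Elob led all genes, but all stood higher in 11 or 12 of 12 other classes too. Lsmem1, the heat shock gene Hspa1b (311 against 1542 CPM), AW011738 and Dusp1 (498 against 1775 CPM) stood lowest. The dissociation list stood at -0.55 (-0.57 to -0.51), below each random list, as it did in the neutrophil-like (-1.10 (-1.18 to -0.99)) and T-like cells (-0.80 (-0.94 to -0.72)), with Hspa1b and Hspa1a leading.

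Neutrophil-like cells of the control tumour lay in cluster 0, and those of the treated tumour in clusters 1 and 3; Ptgs2, Il1a and Cxcl3 below are among the leading genes of these clusters. Neutrophil genes had a median of 0.56 (0.55 to 0.60), above 93.9% of random lists. Of 20 members, 9 stood higher and 6 lower. The granule genes of immature neutrophils stood lower over the class, Ltf (78.0 against 533 CPM; 6.83-fold lower, 6.37 to 7.34), Ngp (154 against 1040.3 CPM) and Camp (131 against 601), but this rested on the 52 cells of cluster 34. Without them the control values were 79.2, 54.6 and 18.5 CPM, so that Ngp and Camp stood higher in the treated tumour and Ltf at about the same level. Ptgs2 (3136 against 8286 CPM) stood lower. Inflammatory myeloid genes had a median of 0.57 (0.55 to 0.58), above 93.7% of random lists. Of 17 members, 8 stood higher and 3 lower. Among them Cxcl3 (1190.3 against 279.8 CPM; 4.25-fold higher, 4.08 to 4.43) and interleukin-1 alpha, Il1a (1425 against 604 CPM; 2.36-fold higher, 2.29 to 2.43), stood higher and Il6 (4.02 against 20.03 CPM) lower, the last not past free RNA. AY036118, Stfa1, Gng5 and Cxcl3 led all genes; all but Stfa1 stood higher in 11 or 12 of 12 other classes too. Hspa1b, Ltf, Ngp and Ifitm6 (17.0 against 108 CPM) stood lowest, and Ifitm6 was at 21.8 CPM in the control without cluster 34. In T-like cells the cytotoxic and checkpoint genes had a median of 0.26 (0.18 to 0.49), above 85.2% of random lists. Short transcripts exceeded long ones by 0.759. Of 18 members, 8 stood higher and 0 lower. The chemokine Ccl5 (1912 against 353 CPM; 5.41-fold higher, 5.18 to 5.66) and the granzymes Gzma (463 against 172 CPM; 2.69-fold higher, 2.52 to 2.89) and Gzmb (412 against 175 CPM) stood higher. Ccl5 did so in all 13 classes and leads cluster 8, which held 1003 of 2523 treated and 568 of 2399 control T-like cells. Cluster 5 held 1057 and 1437 and cluster 19 held 317 and 222. Lowest in the list was the exhaustion-associated Tox (83.4 against 150.1 CPM), at -0.42 relative to all genes. Regulatory and Th17 genes had a median of 0.51 (0.45 to 0.61), above 98.2% of random lists. Among them Il17a (26.2 against 8.18 CPM; 3.21-fold higher, 2.35 to 4.45) and amphiregulin, Areg (242 against 101 CPM), stood higher and Il10 (4.45 against 15.1 CPM) and the regulatory T cell factor Ikzf2 (570.4 against 1136 CPM) lower. The histone genes Hist1h1b, Hist1h4d and Hist1h2ae and granzyme F, Gzmf (51.7 against 7.04 CPM), led all genes; the histone genes stood higher in 9 of 9, 7 of 8 and 6 of 7 other classes too. Hspa1b, Mtss1 and Hspa1a were among the lowest.

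Epithelial-like cells of the treated tumour carried more epithelial identity transcripts, at a median of 0.60 (0.57 to 0.62), above 99.3% of random lists. Of 17 members, 9 stood higher and 2 lower. Short transcripts exceeded long ones by 0.676 here, more than that median. Epcam (463 against 88.4 CPM; 5.24-fold, 4.94 to 5.55) and the claudins Cldn3 (89.1 against 17.96; 4.96-fold, 4.36 to 5.66) and Cldn7 (96.7 against 26.0) stood higher and E-cadherin, Cdh1 (327 against 703; 2.15-fold, 2.08 to 2.23), lower. EMT genes had a median of 0.04 (-0.08 to 0.07), above 48.4% of random lists, with Snai2 (4.44 against 9.41 CPM), Axl (76.3 against 138) and Zeb2 (46.6 against 82.2) as its lowest members. Chemokines had a median of 0.11 (0.03 to 0.19; -0.20 before the shift), above 76.1% of random lists. Of 22 members, 7 stood higher and 4 lower. Here Ccl5 (67.5 against 11.7 CPM), Cxcl3 (93.8 against 25.6) and Cxcl5 (522 against 169.6 CPM; 3.07-fold higher, 2.94 to 3.21) stood higher and Cxcl14 (1.40 against 9.47 CPM) lower. Under the TMM-type factor that median before the shift was 0.03. Inflammatory myeloid genes had a median of 0.54 (0.46 to 0.69), above 99.9% of random lists, led by Nos2 (17.2 against 1.65 CPM; 10.4-fold higher, 6.98 to 16.2). Proliferation genes stood at -0.11 (-0.17 to -0.06), above 19.3% of random lists. Clca3b, Wfdc18, keratin 14, Krt14 (46.9 against 4.40 CPM), and lactotransferrin, Ltf (189.7 against 21.6 CPM), led all genes. The lipoprotein gene Apoc2 (12.7 against 169 CPM; 13.3-fold lower, 11.3 to 15.7), Mucl3, Gsta1 and Lsmem1 stood lowest. In endothelial-like cells interferon response genes stood higher, at a median of 0.54 (0.34 to 0.65), above 99.8% of random lists. Of 16 members, 8 stood higher and 0 lower, led by Ifi27l2a (149 against 48.1 CPM) and Ifit3 (16.6 against 4.96), of which Ifi27l2a stood higher in all 13 classes. Matrix genes stood lower, at -0.70 (-0.88 to -0.38), below each random list. Of 24 members, 0 stood higher and 13 lower, but Col1a1 (12.9 against 98.6 CPM) and Col1a2 (13.8 against 97.6) were wholly within free RNA in both libraries. Blood vessel genes had a median of -0.01 (-0.17 to 0.06), above 45.8% of random lists. The tip cell genes Apln (93.8 against 197 CPM) and Esm1 (126 against 248 CPM; 1.97-fold lower, 1.70 to 2.29) and Vcam1 (145 against 247 CPM) and Angpt2 (115 against 179) were the lowest members. Ptn, Fmo2, Hist1h1b and the complement inhibitor Serping1 (155 against 30.2 CPM) led all genes. Foxp2, Pcdhga12 and Eln (63.0 against 238 CPM) were among the lowest.

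In simulated counts of tumour fibroblast-like cells the naming rule recovered 98% of genes changed 2-fold and no unchanged ones, so counting error is small. Treatment cannot be told from any other difference between 2 single tumours: the calcineurin/NFAT response list stood below the median of all genes in the 12 other classes as well (-1.20 to -0.09), and the trend with transcript length ran through each class.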

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

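The equal doublet share, the totals without Gm42418 and mitochondrial genes, and the values relative to genes of like transcript length or to the other classes were chosen after the results had been seen. A value counts as moved when it leaves its 95% counting interval. No paired analysis was possible because each group has 1 library and the labels pair none. The cause was not tested for any change below, except where the construction of the alternative gives it.

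Of 56 share ratios under the alternatives, 40 stayed within the interval, 14 moved and 2 turned. For the AF12198-treated over the control tumour, the fibroblast-like ratio (0.395) was 0.334 with the stricter filter and the endothelial-like ratio (0.710) stayed within its interval throughout. The macrophage/monocyte-like ratio (0.884) turned to 1.03 with the stricter filter and was 0.821 with no filter and 0.935 at resolution 2.0. The neutrophil-like ratio (1.252) was 1.14 with the stricter filter and 1.31 with doublets kept, the T-like ratio (1.07) 1.34 with the stricter filter and, turned, 0.840 at resolution 0.5, and the epithelial-like ratio (0.937) 0.844 with no filter. For the ligated over the normal pancreas, the fibroblast-like ratio (4.68) was 3.57 with the stricter filter, 3.06 with doublets kept and 3.04 and 3.04 at resolutions 0.5 and 2.0. The macrophage/monocyte-like ratio (9.29) was 4.76 with the stricter filter and the epithelial-like ratio (0.872) 0.567 with it and 0.493 at resolution 0.5, while the endothelial-like ratio (0.669) stayed within its interval.

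Of 112 list medians under the alternatives, 81 stayed within the interval, 24 moved and 7 turned. Reported values in brackets are log2 ratios before the shift of all genes is taken off. The values relative to genes of like length or to the other classes have a shift taken off by construction, so part of each move or turn under them is that shift. In fibroblast-like cells of the treated over the control tumour, the TMM-type factor gave -0.14 for the inflammatory CAF list (-0.35 as reported), 0.45 for the myofibroblastic list (0.24), -0.069 for IL-1/NF-kB targets (-0.27) and -0.39 for the calcineurin/NFAT response (-0.59). This factor takes most of the shift away by construction. Relative to genes of like transcript length they were -0.18, 0.38, -0.19 and -0.21, beside -0.085, 0.51, -0.0041 and -0.32 relative to all genes. An equal doublet share gave -0.27 and 0.28 for the CAF lists, and each cell weighted equally -0.16 and -0.45 for the other 2. Relative to the other classes the myofibroblastic median was 1.01, and the inflammatory, IL-1/NF-kB and calcineurin/NFAT medians turned to 1.17, 0.017 and 0.58; free fibroblast RNA counted in the other classes enters this alternative by construction.

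In the treated over the control tumour, inflammatory myeloid genes of macrophage/monocyte-like cells (-0.0055) stood at 0.34 with the TMM-type factor, 0.23 relative to genes of like length, -0.038 with the stricter filter, 0.097 with none, -0.043 with doublets kept and -0.092 relative to the other classes. Chemokines of epithelial-like cells (-0.20) turned to 0.032 with the TMM-type factor and 0.19 relative to the other classes, and were -0.34 with each cell weighted equally and -0.015 relative to genes of like length. In fibroblast-like cells of the control tumour over the ligated pancreas, the inflammatory list (0.12) turned to -0.033 without Gm42418 and mitochondrial genes and -0.044 relative to genes of like length, and was 0.39 with each cell weighted equally. This list lay at the median of all genes (0.0099 relative to it), and the first 2 alternatives rescale or shift all genes, which turns such a value. The myofibroblastic list (1.53) was 1.31 with a pseudocount of 10 CPM, which shrinks ratios of low genes by construction, and in the ligated over the normal pancreas (1.65) it was 1.03. The inflammatory list of that comparison (0.72) stayed within its interval throughout.

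Of the 4910 values of single genes under the alternatives, 3809 stayed within the interval, 1070 moved and 31 turned. With free RNA subtracted, genes that turned for the control tumour over the ligated pancreas were Il1b in epithelial-like (-4.09), endothelial-like (-0.088), T-like (-1.60) and neutrophil-like cells (0.042), Tnf in fibroblast-like cells (-1.73) and H2-Aa in endothelial-like cells (-1.62). For the treated over the control tumour they were Il6 in neutrophil-like (0.47), Il1b in T-like (0.92) and Nfatc4 in macrophage/monocyte-like cells (0.14), and for the ligated over the normal pancreas Saa3 in epithelial-like cells (-0.46). In the treated over the control tumour the TMM-type factor turned Il1b in epithelial-like (0.11) and neutrophil-like cells (0.25), Nfatc1 in macrophage/monocyte-like (0.14) and Nfatc3 in T-like cells (0.055). Relative to genes of like length, Nfatc4 in fibroblast-like (0.042), Nfatc1 and Ciita in macrophage/monocyte-like (0.26 and 0.017), Il1b in neutrophil-like (0.045) and Nfatc3 and Nfatc1 in T-like cells (0.12 and 0.00071) turned. Both alternatives take off a shift by construction; relative to all genes Nfatc1 in macrophage/monocyte-like (0.10), Il1b in epithelial-like (0.18) and neutrophil-like (0.18) and Nfatc3 in T-like cells (0.017) already stood above 0. With each cell weighted equally, Il6 in endothelial-like (-0.12) and Il1b in neutrophil-like cells (0.32) turned in the control tumour over the ligated pancreas. An equal doublet share turned H2-Eb1 in fibroblast-like cells (-0.38) and Retnlg, Mmp9, Rbp4 and Hist1h1b in erythroid-like cells (-2.08, -5.56, -0.48 and -3.42), of which Retnlg (-1.22), Rbp4 (-2.75) and Hist1h1b (-0.28) turned with no cell filter too. Onecut2 in B-like cells turned with the stricter filter (-0.42). Without Gm42418 and mitochondrial genes 25 values of single genes moved and 0 turned, and with a pseudocount of 10 CPM 211 moved and 0 turned. Depth limits the ligated library most, where 61 T-like cells give 3 counts the weight of 51.7 CPM for Il6.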

Other observations

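Among the smaller classes, the AF12198-treated tumour held more acinar-like (1.73% against 0.291%; 5.93 (4.46 to 8.03) times) and mast or basophil-like cells (0.927% against 0.182%; 5.10 (3.53 to 7.55)) than the control tumour. It held fewer plasma-like (0.360% against 1.55%; 0.232 (0.175 to 0.302)), erythroid-like (0.185% against 1.71%; 0.108 (0.0742 to 0.154)) and B-like cells (0.751 (0.661 to 0.853)), and about as many dendritic-like (1.01 (0.913 to 1.11)) and natural killer or innate lymphoid-like cells (0.975 (0.835 to 1.14)). Mast or basophil-like cells carried less of the T helper 2 cytokine Il4 (70.8 against 646 CPM; 9.13-fold lower, 5.99 to 14.1) and of Csf2 (7.45 against 180.1 CPM; 24.2-fold lower, 7.88 to 98.7). The chemokine Ccl5 (722 against 123 CPM; 5.89-fold higher, 5.39 to 6.44) led in dendritic-like cells. In natural killer-like cells Ccl5 (5227 against 1077 CPM; 4.85-fold higher, 4.48 to 5.27) stood higher too, after Slfn1, AY036118 and Gng5. There Chil3 (at least 11.7-fold lower), Gdf15, Mcpt1 and Wdr13 stood lowest, and Slfn1 came to 0.17 from 2.70 with doublets kept. Dendritic-like cells further led with Hist1h1b, Hist1h4d and Gng5, and stood lowest in Lsmem1, Hspa1b (396 against 2409.9 CPM), Dusp1 and Csrnp1. Acinar-like cells led with Gzmc and the globin genes Hbb-bt, Hbb-bs and Hba-a2, and stood lowest in the protease Mmp3 (0.420 against 144 CPM), Hes1, Aldh1a3 and the claudin Cldn18 (4.198 against 140.5 CPM). B-like cells led with Onecut2, Mid1, AY036118 and Fmc1, and stood lowest in Hdac7, Retnlg, Pclaf and Parp11. Plasma-like cells led with Hist1h1b, Hist1h1e, Cd52 (2389.7 against 567 CPM; 4.21-fold higher, 3.94 to 4.50) and Hist1h2ae, and stood lowest in the globin genes Hba-a2, Hba-a1, Hbb-bt and Hbb-bs. Mast or basophil-like cells led with Wfdc18, Ccdc59, Ccr7 and Ahnak2, each at 0 UMIs in the 35 control cells, and stood lowest in Hba-a2, Csf2, Hba-a1 and Il4; Wfdc18 came to 0.00 at an equal doublet share. Erythroid-like cells led with Retnlg, Mmp9, Rbp4 and Hist1h1b, which depend on the doublets removed, and stood lowest in Rgs16, R3hdm2, AW011738 and Me1, each at 0 UMIs in the 35 treated cells.

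The genes named in advance had these ranges over the 7 classes and both tumours, in CPM. Il1r1 ran from 0 (natural killer-like control and treated, plasma-like treated, mast-like control and treated) to 7.20 (acinar-like, control). Il1b ran from 475 (plasma-like, treated) to 4187 (dendritic-like, control). Il6 ran from 0.420 (acinar-like, treated) to 2765 (mast-like, control). Cxcl1 ran from 10.6 (mast-like, control) to 145 (erythroid-like, control). Nfatc1 ran from 10.9 (acinar-like, treated) to 424 (mast-like, control). Nfatc2 ran from 2.94 (acinar-like, treated) to 50.9 (natural killer-like, treated). Nfatc3 ran from 3.60 (acinar-like, control) to 379.6 (B-like, control). Nfatc4 ran from 0 (acinar-like control and treated, dendritic-like treated, natural killer-like treated, B-like treated, plasma-like treated, mast-like control and treated, erythroid-like control and treated) to 4.57 (natural killer-like, control). A 0 there allows up to 31.8 CPM at the floor of 3 counts. Other genes of the interleukin-1 system are given for the ligated, control and treated libraries in order. The decoy receptor gene Il1r2 was highest in neutrophil-like cells, at 2778, 3671 and 2053 CPM. The antagonist Il1rn stood there at 2375, 4452 and 4191, and Ptgs2 at 5465, 8286 and 3136. In macrophage/monocyte-like cells Il1rn stood at 559, 1747 and 1036 and Il1a at 13.4, 115 and 207. Fibroblast-like cells of the 4 libraries, with the normal pancreas first, had Il1a at 0 (up to 5.20), 0 (up to 1.56), 10.8 and 24.9 and the calcineurin regulator Rcan1 at 22.5, 129, 127 and 168. Of the lists not given above, in fibroblast-like cells of the treated over the control tumour STAT3 response genes had a median of -0.19 (-0.24 to -0.05), above 3.05% of random lists, and glycolysis and hypoxia genes 0.05 (-0.03 to 0.16), above 42.3% of random lists.

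In the 3 patterns that follow, all taken from the treated over the control tumour, the tests of shared sequence, overlapping genes and free RNA for the first were set out before their result was seen; the test of transcript length there and each test of the other 2 patterns only afterwards. The test of free acinar RNA was set out afterwards too. The biological explanation in each, treatment with AF12198, was not tested apart from the tumour and the library, since each group is 1 library.

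The first pattern is that single genes stood on the same side in every class that measured them, though at differing ratios. Of 10571 genes counted in at least 6 of 13 classes, 304 stood at least 1.5-fold higher and 26 lower in each, relative to all genes. Log2 ratios of the 6 main classes correlated at 0.575 to 0.784 over 9452 genes. Near-identical copies argue little here: 56 of the 304 higher genes (18.4%, 14.2 to 23.2; 4.93% of matched genes) share 50% or more of their 3' words with another gene, and 3.95% have another gene on the same strand over the last exon, so most have neither. Subtraction of free RNA left 98.7% of the median absolute ratio, but barely moves genes near their pooled level, so free RNA stays open. For the 20 of the 304 at least 10 times higher in acinar-like cells, 59.8% was left (log2 1.37 from 2.29), so free acinar RNA cannot be told apart there. Transcript length is a candidate explanation: the difference between genes under 1000 and over 3000 bases was at least 0.630 on the log2 scale in each class, and 71.1% of the 304 (65.6 to 76.1; 17.8% of matched genes) lie under 1000 bases.

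The next pattern is the calcineurin/NFAT response list standing low in fibroblast-like cells. Its median relative to all genes was -0.32, and it stood below 0 in each of the 12 other classes, from -1.20 to -0.09, at or below the fibroblast-like value in 10 of them, so a difference between the libraries in every class may account for it. Handling stress cannot be told apart: without the immediate-early members the median was -0.037 (-0.20 to 0.14), with 5 of 10 members below 0. Transcript length does not account for all of it, since relative to genes of like length the median stayed at -0.21 (-0.30 to -0.12), with 11 of 16 members below 0. A fibroblast-specific effect of blocking IL1R1 on this list is therefore not shown by these data.

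The last pattern is the lower share of fibroblast-like cells in the treated tumour. Fibroblasts lost to the filter or to other names would still count over all deposited barcodes, but there the fibroblast markers (15 genes, Thy1 left out, since T cells express it) stood lower too, at a median of -1.16 (-1.17 to -1.15) relative to all genes. More neutrophil-like cells do not account for it: without them the shares were 10.2 and 4.58%, a ratio of 2.24 (2.02 to 2.48) of control over treated. More pancreas outside the tumour goes with the higher share of acinar-like cells and the 7 endocrine-like cells against 0. As the whole cause it would also dilute macrophage/monocyte-like and T-like cells, which both pancreas libraries held less of (1.86 and 17.0% of cells that are not neutrophil-like, against 55.0% in the control tumour). Their share was 58.8% in the treated tumour, 1.07 (1.04 to 1.11) times that of the control, so a part only stays open. Of the same cells 5.42 and 28.1% were fibroblast-like in the normal and ligated pancreas, so tissue like the ligated pancreas would raise the share. A difference in digestion, in the piece of tumour taken or in treatment stays open.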
